A study of Mus musculus with 2 samples.

How the data were processed

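H3K36me3 was measured by ChIP-seq in forebrain tissue of mouse embryos (strain B6NCrl, embryonic day 11.5) in 2 biological replicates, per the labels. Replicate 1 is a pool of 109 embryos with 1 technical replicate and replicate 2 a pool of 88 embryos with 3 technical replicates, and both pools hold males and females, per the labels. The replicates are separate pools of embryos of 1 group, so no comparison between groups could be made.

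The authors deposited 4 narrowPeak lists on assembly mm10, per the labels and the deposited file descriptions. Peaks were called for each replicate alone and for both replicates together (the pooled list), and a replicated list was derived from those 3, per the deposited file descriptions. Each call also used 2 further input files that the descriptions do not explain, the same 2 in every case. The aligner, the peak caller, their settings and the rule that makes a peak replicated are not given in the sources used here. Each deposited peak has the authors' signal value, an enrichment whose reference is not stated, and the authors' −log10 p and −log10 q. The smallest −log10 p in the deposited lists was 2.0, so weaker enrichment is not listed. These peak values are the authors' own and were used only to describe, rank or filter peaks within a list. The lists hold no read counts, so the depth of each replicate is unknown and no interval or floor that needs it is given. A longer list can come from deeper sequencing, from better enrichment or from more of the mark, and a gene with no peak is not shown to lack the mark. Signal tracks and alignments were not analysed here.

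Peak positions were joined to GENCODE mouse release M21 on GRCm38, the assembly that mm10 names. Chromosome names matched, and every peak on an assembled chromosome ended within its length. Overlapping peaks of a list were merged before bases were counted. A gene's covered share is the percentage of bases from its annotated start to its end that lie under merged peaks, on either strand, since peaks carry no strand. Protein-coding genes with at least 10% covered were called marked. Bases were assigned to 1 class each, and a base in several classes took the first in the order that follows. The order was promoter (within 1 kb of the start of a protein-coding gene), coding exon, 5′ UTR, 3′ UTR, non-coding exon, intron and intergenic. Chance levels came from 100 circular shifts of a list within each chromosome, which keep the lengths and spacing of peaks and leave out the first 3 Mb of each chromosome (20 shifts for the number of marked genes). Profiles used protein-coding genes of at least 5 kb in 10 equal bins, with 1000 bootstrap resamples of genes for 95% intervals. The mean and SD over replicates use each replicate's own list, and the replicated list gives the main value.

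Gene lists were compared with all other protein-coding genes by an exact conditional test of the number of marked members within 10 strata of gene length, two-sided, with Benjamini-Hochberg adjustment over the 22 lists. The same exact test compared X-linked with autosomal and single-exon with multi-exon genes, with the olfactory receptor genes left out of both, the Y left out of the first and genes with no exon in a protein-coding transcript left out of the second. Fisher's exact test compared neural lists with lists of other tissues. Exons and introns were compared by 100000 random sign flips of the differences per gene, which test their mean. Genes are not independent replicates, so these p-values describe the lists of peaks and not the spread between embryos. No test across the 2 replicates was made, and an exact permutation test over 2 values cannot reach 0.05.

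The 22 lists were fixed before the data were examined, as were the tests, the 10% threshold, the rule for naming genes and all alternatives but 4. These keep only replicated peaks found in both replicates or, for the neural comparison, use length strata, add the synapse list or leave out the progenitor list. The lists were housekeeping, spliceosome, cell cycle, writers, erasers and readers of H3K36 methylation of any degree with linked elongation factors, neural progenitor, forebrain regional transcription factors, early neuron, synapse and mature neuron, mature glia, midbrain and hindbrain, Hox, erythroid, endothelial, macrophage, mesenchyme, skeletal muscle, heart, liver, imprinted, X inactivation and Y, Zfp genes and Olfr genes. Named genes are the 2 highest and 2 lowest members of each list by covered share, with any member of the lists of H3K36 methylation and of X inactivation. The rule adds the 10 genes with the largest covered length, the 10 with the highest covered share, the 10 with the largest difference between replicates at equal numbers of peaks, 5 non-coding genes, 5 intergenic clusters and the 3 longest peaks. Other members of a list, marked X-linked genes and single-exon genes were named after their values were seen. The Srrm2 region was drawn because it holds 1 of the 3 longest peaks.

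The calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. They were tested on simulated data first. Covered bases matched a base-by-base count in 500 of 500 intervals. Of 500 random lists of 22 genes, 2.4% gave p under 0.05. Lists of 22 genes with a true marked share of 20%, 30% and 50% gave p under 0.05 in 42.5%, 82% and 99.5% of draws. None of 10 random peak lists (0) was called enriched in genes. Alternatives were the pooled list, each replicate's own list, replicate 2 at replicate 1's number of peaks, peaks with −log10 q over 2 or over 4, other thresholds for marked and for shared, no length strata, and genes without overlap. Peaks on unplaced scaffolds were left out of every count by gene.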

Results

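H3K36me3, a trimethylation of histone H3 that the enzyme Setd2 lays down along the bodies of transcribed genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the forebrain of mouse embryos at embryonic day 11.5. At this stage the forebrain is mostly dividing neural progenitors with the first neurons. There was 1 group of 2 biological replicates, each a separate pool of forebrains from male and female embryos (109 embryos in replicate 1 and 88 in replicate 2). With no second tissue, stage or antibody, the design asks where the mark lies, which genes carry it, and how far the 2 pools give the same picture. The deposited measurements are 4 peak lists, and the number of sequenced reads behind them is unknown. All positions are on mouse assembly mm10, and a gene is called marked where at least 10% of its body, from annotated start to end, lies under peaks.

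Srrm2, a gene for a large splicing factor on chromosome 17 from 23790532 to 23824741, shows how the lists relate. Peaks covered 23.9% of Srrm2 in replicate 1, 43.7% in replicate 2 and 34.5% in the replicated list, which the authors derived from the other lists. The window around Srrm2 held 12 peaks in replicate 1 and 13 in replicate 2. A single replicated peak of 6473 bp, from 23814848 to 23821320, covered most of its largest exon, and 95.8% of that peak was coding sequence. The first part of the gene held few peaks in any list.

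**Figure D1:**
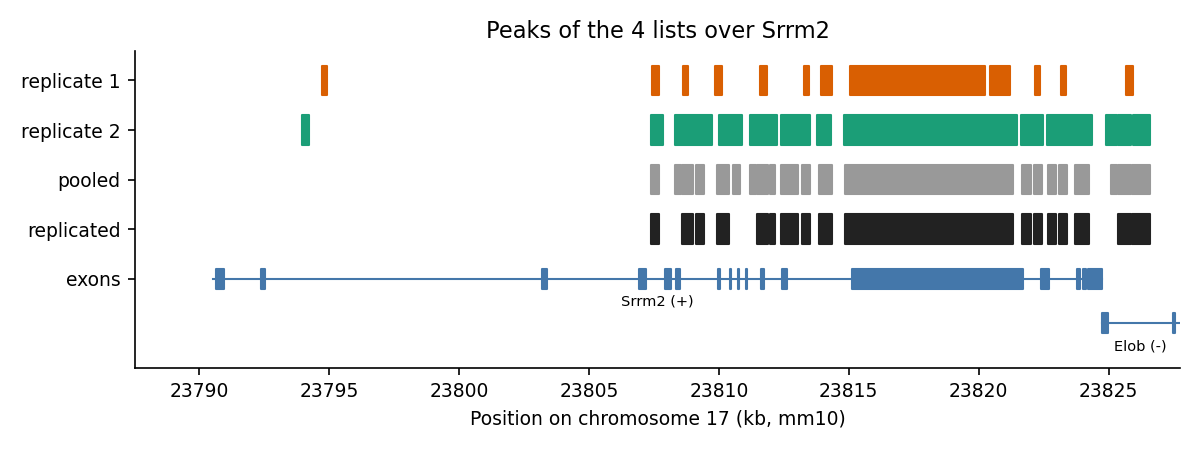
Peaks of the 4 lists over Srrm2 on chromosome 17; the horizontal axis is the position in kb on mm10, each filled block is a peak, and the lowest tracks are the exons of Srrm2 (+ strand) and of its neighbour Elob (- strand). The longest peak in each list lies over the largest exon, with a length of 5.195 kb in replicate 1, 6.661 kb in replicate 2 and 6.473 kb in the replicated list.

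Across the genome the replicates differed several-fold in how much was called, and most peaks of the shorter list lay under those of the full longer one. Replicate 1 had 31492 peaks that covered 8.70 Mb (0.319% of the genome), and replicate 2 had 176997 peaks that covered 60.9 Mb (2.23%), 5.62 times as many peaks over 7.00 times the length. The mean was 104244 ± 102888 peaks (SD, n = 2). Median peak lengths were 230 and 254 bp, and the median signal value was 3.39 in both. The authors' pooled list held 54149 peaks (18.6 Mb) and the replicated list 33174 (13.7 Mb), all of which are also peaks of the pooled list. Replicate 2 covered at least 50% of 73.7% of the replicate 1 peaks, against a mean of 2.69% and a maximum of 3.43% when 1 list was shifted along the chromosomes (one-sided permutation p = 0.0099, the smallest that 100 shifts can give). The bases shared were 10.1% of all bases covered in either replicate, against at most 0.393% after shifting (one-sided permutation p = 0.0099), and 16.8% when the lists were cut to the same number of peaks. With that cut, the share of replicate 1 peaks at least 50% covered by replicate 2 fell to 41.6%. Of the replicated peaks, 21181 (63.8%) overlapped peaks of both replicates by at least 50% of either peak, 11862 those of replicate 2 only, 127 those of replicate 1 only, and 4 neither. No base of 11536 replicated peaks (34.8%) lay under a replicate 1 peak.

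Replicated peaks lay almost entirely inside genes. Of the bases they covered, 19.9% were coding exon, which makes up 1.21% of the genome, a 16.4-fold excess (mean of the replicates' own lists 15.3% ± 4.69, SD, n = 2). The 3′ UTRs took 7.92%, 6.60 times their genome share, and exons of non-coding transcripts 7.49%, 4.16 times theirs. Introns took 60.3% (64.8% ± 4.75 over the replicates, SD, n = 2) against 39.6% of the genome. Promoters, within 1 kb of the start of a protein-coding gene, held 0.442% of covered bases against 1.52% of the genome. Intergenic sequence held 3.76% against 54.6%. In all, 96.2% of the bases under replicated peaks lay in gene bodies, as did 95.4% in replicate 1 and 94.2% in replicate 2, while shifted lists gave a mean of 49.1% and at most 52.2% (one-sided permutation test with 100 shifts, p = 0.0099).

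Along gene bodies the mark was lowest at the start and highest near the end. Over 17798 protein-coding genes of at least 5 kb, the share of bases under replicated peaks in 10 equal bins was 0.269% in bin 1 at the gene start, 4.62% in bin 9 and 4.15% in bin 10. Among the 1718 marked genes of that length it was 1.29% in bin 1, 33.0% in bin 9 and 26.3% in bin 10. Bins 6 to 10 were covered more than bins 1 to 5, 4.09% against 1.64%, a difference of 2.45 percentage points (95% bootstrap interval over genes 2.33 to 2.58). The difference was 1.41 points in replicate 1 and 6.72 points in replicate 2, so its size followed the length of the list, and its direction was toward the gene end in both. No test across the 2 replicates was made.

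**Figure D2:**
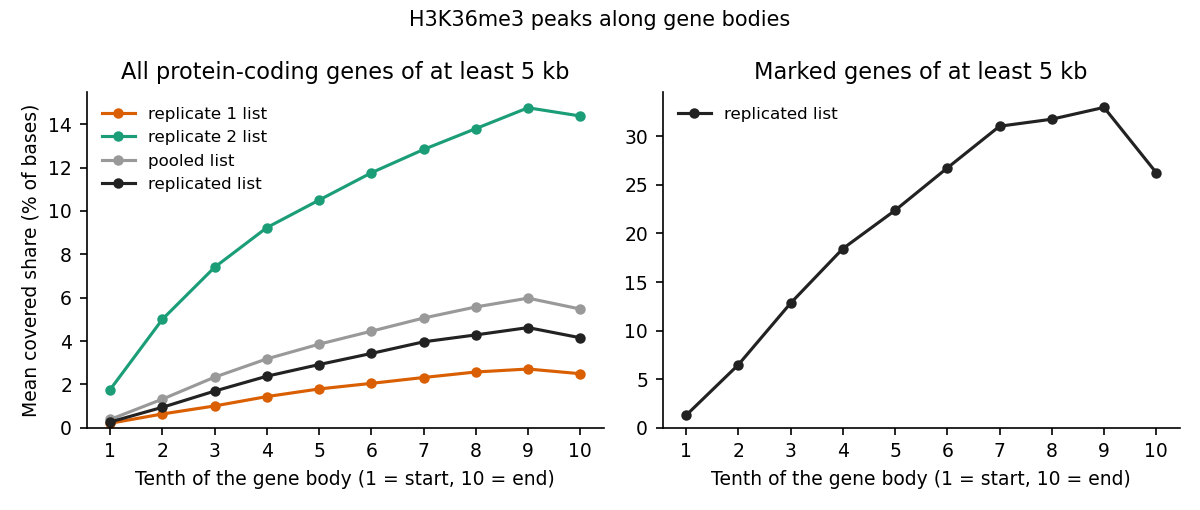
Mean share of bases under H3K36me3 peaks (%, vertical axis) in each of 10 equal bins of the gene body from start to end (horizontal axis), for all 17798 protein-coding genes of at least 5 kb in the 4 lists (left) and for the 1718 marked ones in the replicated list (right). Each line is higher in bin 9 than in bin 1, 4.62% against 0.269% in the replicated list, and lower again in bin 10.

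Some genes lay under peaks for most of their length. By covered share, the 10 highest protein-coding genes of at least 5 kb were Zfp606 (75%), Fasn (72.3%), Ccdc177 (69.3%), Prrc2a (69.2%), Hjurp (68.5%), Zfp105 (68.1%), Zfp146 (67.1%), Zfp90 (61.9%), Sf1 (60.9%) and Hnrnpab (60%). Fasn encodes fatty acid synthase, Hjurp the chaperone of centromeric histone H3, and Sf1 and Hnrnpab RNA-binding proteins, and the Zfp genes encode zinc finger proteins. The replicates' own lists gave 73.3% ± 13.5 for Zfp606 (chromosome 7, 12478293 to 12496235), 70.7% ± 9.76 for Ccdc177 and 62.2% ± 34.2 for Fasn (SD, n = 2). By covered length the highest were Chd2, a chromatin remodeller, with 34.6 kb (30.1% of the gene), Ubr4 with 29.0 kb, Gtf2i with 27.9 kb, Nedd4 with 27.0 kb, Dync1h1, the heavy chain of cytoplasmic dynein, with 26.7 kb, Syne2 with 25.8 kb, Smarca4 with 25.2 kb, Trrap with 24.2 kb and Myh10 with 24.1 kb. Gm20388 had 70 kb, but it is a read-through model of 4434.88 kb that spans many other genes, and only 1.58% of it was covered. In total 1921 of 21938 protein-coding genes (8.76%) were marked, against a mean of 356.5 and at most 398 after 20 shifts of the list. Replicate 1 alone marked 943 genes and replicate 2 alone 6383, so the count depends on which replicate is used. Of the 943, 941 (99.8%) were among the 6383, where 274.4 would be shared by independent lists, and 891 (94.5%) were still marked when replicate 2 was cut to the same number of peaks.

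With both lists at the same number of peaks, replicate 2's still covered 19.4 Mb (mean peak length 616 bp) against 8.70 Mb (276 bp), so differences per gene lean toward replicate 2 by construction. The largest differences in covered share among genes of at least 5 kb were all toward replicate 2, in Mybbp1a (52.7 points), Hspa5, the main chaperone of the endoplasmic reticulum (50.8), Eef1g (50.1), Fasn (46.3), Phykpl (45.2), the ribosomal protein genes Rps7 (44.3) and Rpl24 (43.7), Tbrg4 (43.3), Cdc25a (43.0) and Psmd7 (42.7). Each of these genes except Rpl24 (3.86%) was marked in replicate 1 too, with for example 38% of Fasn, 25% of Hspa5 and 10.4% of Eef1g under its peaks. Phykpl overlaps Hnrnpab on the other strand, and peaks carry no strand. With 1 pool per value, these differences have no test.

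Among 22 fixed gene lists, those of dividing cells and of RNA processing were marked far more often than genes of the same length. Of 22 spliceosome genes 20 were marked, where 2.63 were expected from gene length, with 54.4% of Prpf8 (chromosome 11, 75486816 to 75509449; 53.5% ± 34.5 over the replicates, SD, n = 2) and 41.6% of Ddx17 covered. The 2 unmarked members were Prpf6 (7.35%) and Srsf11 (5.82%). Of 25 cell cycle genes 21 were marked against 2.65 expected, among them the mitotic kinase Plk1 (47.2%; chromosome 7, 122159439 to 122169873; 44.1% ± 35.2, SD, n = 2) and the DNA topoisomerase Top2a (45.3%; chromosome 11, 98992943 to 99024189; 45.7% ± 33.4, SD, n = 2), while Ccnb1 and the X-linked Pola1 had no replicated peak. Of 20 housekeeping genes 11 were marked against 2.21 expected, led by the elongation factor Eef2 (57.5%; chromosome 10, 81176631 to 81182498; 53.6% ± 13.7, SD, n = 2) and the chaperone Hsp90ab1 (56.0%; 56.9% ± 22.7, SD, n = 2). The X-linked Hprt and Pgk1 and the autosomal Gapdh and Eef1a1 had no replicated peak. Adjusted p-values were 1.44e-16 for the spliceosome, 4.21e-17 for the cell cycle and 6.81e-06 for housekeeping genes (two-sided exact conditional test in strata of gene length, Benjamini-Hochberg over the 22 lists). Replicate 1 marked 13 of the spliceosome, 10 of the cell cycle and 9 of the housekeeping genes, and replicate 2 marked 22, 24 and 17, so the counts depend on the replicate, while each of the 3 lists passed the test in both. Cell cycle genes lost the call when only peaks with −log10 q over 4 were used, where 0 of 25 were marked.

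Zinc finger genes were marked more often than their length predicts, and olfactory receptor genes less often. Of 397 protein-coding genes whose symbols begin with Zfp, 111 (28.0%) were marked where 46.2 (11.6%) were expected, with Zfp606 and Zfp105 at the top and the long genes Zfp804b and Zfpm2 without a replicated peak. Replicate 1 marked 79 of them and replicate 2 marked 236. None of 1135 olfactory receptor (Olfr) genes, which olfactory sensory neurons express, was marked in any list, where 112.6 were expected from length in the replicated list. Adjusted p-values were 9.08e-19 and 1.98e-55 (two-sided exact conditional test, Benjamini-Hochberg over the 22 lists).

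Neural progenitor genes were marked more often than expected, and the forebrain's regional transcription factors were not. Of 22 progenitor genes 7 were marked against 1.61 expected, namely the intermediate filament genes Vim (41.5%; chromosome 2, 13573927 to 13582826; 36.4% ± 31.4, SD, n = 2) and Nes (20.4%), the RNA-binding Msi1 (36%; chromosome 5, 115429599 to 115455698; 41.5% ± 25.1, SD, n = 2), the Notch pathway genes Dll1 (35.3%), Notch1 (27.2%) and Hes5 (15.9%), and Dbi (26.4%). The progenitor factors Sox1, Sox2 and Sox3, the Notch target Hes1, and Hes6, Fabp7, Ednrb and Zic1 had no replicated peak. The adjusted p was 0.0017 (two-sided exact conditional test, Benjamini-Hochberg over the 22 lists), and replicate 1 marked 6 and replicate 2 marked 12. None of 30 forebrain transcription factor genes was marked (2.81 expected, adjusted p = 0.253 by the same exact test). Lhx2, which is needed for cortex formation, came closest with 9.60% (chromosome 2, 38339281 to 38369733; 15.6% ± 13.2, SD, n = 2), Nr2f1 had 1.67%, and Lhx6 and Lhx8 had none. Of 26 early neuron genes 2 were marked, Map1b (15.9%; 20.8% ± 16.3, SD, n = 2) and Tagln3 (11%; 23.5% ± 21.7, SD, n = 2), against 1.69 expected (adjusted p = 0.823, same exact test), and Reln and Robo2 had no replicated peak.

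**Figure D3:**
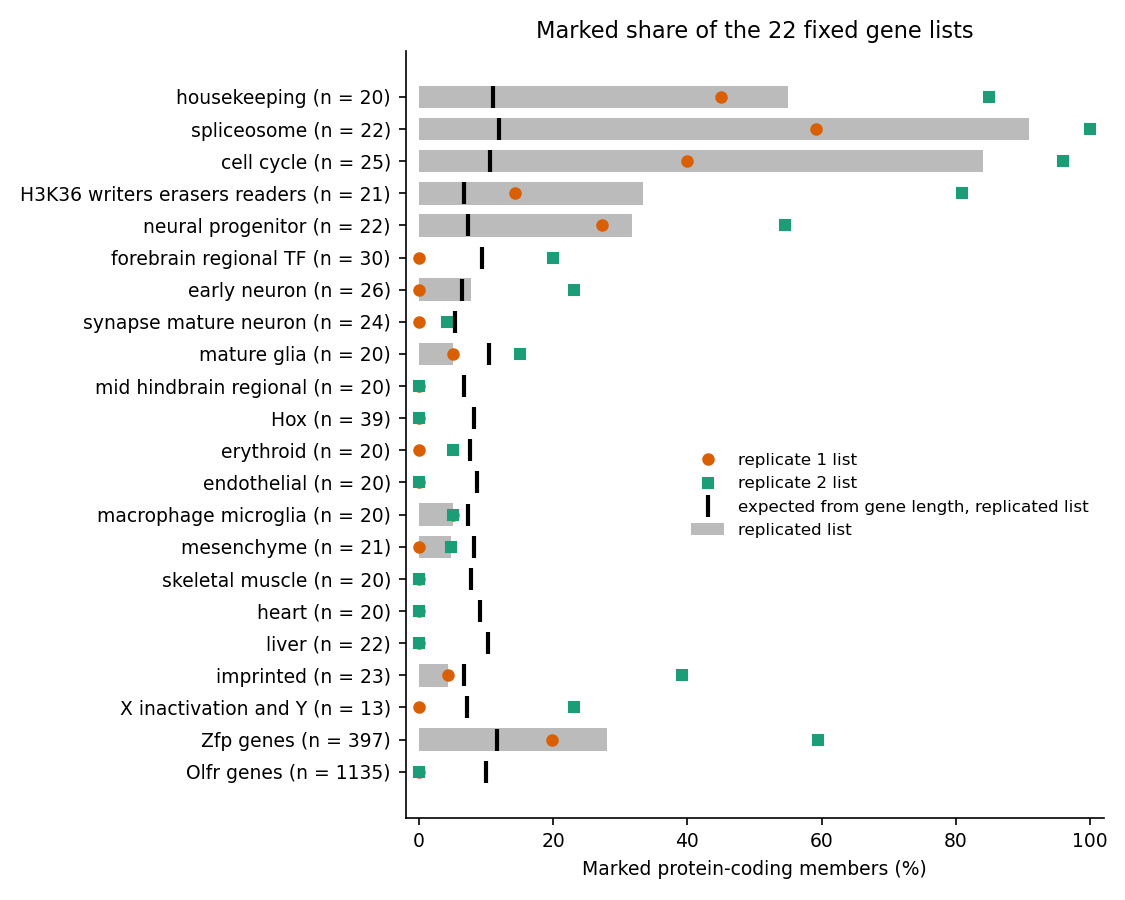
Marked protein-coding members (%, horizontal axis) of each of the 22 fixed gene lists (vertical axis, n is the number of members). Bars are the replicated list, circles replicate 1, squares replicate 2 (which hide circles of the same value) and black ticks the share expected from gene length in the replicated list. Spliceosome (90.9%), cell cycle (84.0%) and housekeeping (55.0%) genes lie far above their ticks, and the Hox and Olfr genes lie at 0 in every list.

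Genes of other tissues, other brain regions and later stages carried few peaks. No gene was marked among 20 erythroid (1.53 expected, adjusted p = 0.573), 20 endothelial (1.73, 0.446), 20 skeletal muscle (1.54, 0.573), 20 heart (1.82, 0.446), 22 liver (2.27, 0.343), 20 midbrain and hindbrain (1.34, 0.573) and 39 Hox genes (3.18, 0.191), and none among 24 genes of synapses and mature neurons (1.28, 0.816; two-sided exact conditional tests, Benjamini-Hochberg over the 22 lists). The highest covered shares in these lists were 8.03% for the transferrin receptor gene Tfrc, 3.95% for Dlg4, which encodes a postsynaptic scaffold, and 0.829% for Mmrn2. Hox genes such as Hoxa3 and Hoxc5 had no peak in either replicate. Among 20 macrophage genes only the lysosomal gene Cd68 was marked (50.3%; 52.6% ± 36.5, SD, n = 2; 1.47 expected, adjusted p = 1), among 21 mesenchyme genes only the fibronectin gene Fn1 (12.5%; 1.73 expected, adjusted p = 1), and among 20 genes of mature glia only Cnp (18.2%; 2.08 expected, adjusted p = 0.823; same exact tests), which overlaps Dnajc7. Among simulated lists with no marked member, drawn once at each size, p before adjustment first fell under 0.05 at 38 members. Most of these lists were thus likely too short for a call. That size does not assure a call, since the 39 Hox genes gave p = 0.0694 before adjustment (same exact test). In replicate 2's full list 10 of the 22 lists were called low in the same exact test, Olfr, Hox (adjusted p = 6.88e-05) and liver (0.000719) among them. Hox was also called low in replicate 2's list cut to replicate 1's number of peaks (0.0467), in the pooled list (0.0469) and at 5% covered (0.0290, same exact test), but not in replicate 1 (0.713).

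Set against each other, genes of the neural lists were marked more often than genes of other tissues, and in the replicated list progenitor genes made up most of the difference. Of 78 genes in the progenitor, regional transcription factor and early neuron lists, 9 (11.5%) were marked, the 7 progenitor genes named above with Map1b and Tagln3. Of 143 genes of blood, vessels, macrophages, mesenchyme, muscle, heart and liver, 2 (1.40%) were marked, Cd68 and Fn1. The difference was 10.1 points (two-sided Fisher's exact test, p = 0.00171). In tests added after the data were seen, 4.04 neural genes were expected from length among the genes of both sides (two-sided exact conditional test, p = 0.00197), the difference was 7.42 points with the synapse and mature neuron list counted as neural (Fisher's exact p = 0.00922), and without the progenitor list it was 2.17 points and not past the threshold (2 of 56 genes; Fisher's exact p = 0.315). It was 7.69% against 0.699% in replicate 1 (Fisher's exact p = 0.00848) and 30.8% against 2.10% in replicate 2 (Fisher's exact p = 1.13e-09), where 12 progenitor, 6 regional transcription factor and 6 early neuron genes were marked. Genes are not independent replicates, so these p-values describe the lists and not the spread between embryos.

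Genes of a fixed list around H3K36 methylation, which holds enzymes that write or remove any of its degrees, readers and linked elongation factors, were marked more often than expected. Of 21 such genes 7 were marked against 1.42 expected, the demethylase Kdm4a (38.4%; chromosome 4, 118136957 to 118180043; 43.3% ± 29.2, SD, n = 2), the elongation factor Supt6 (24.4%), the methyltransferases Nsd2 (23.1%) and Nsd1 (12.6%), and the reader genes Brpf1 (22.7%), Psip1 (11.7%) and Morf4l1 (11.1%). Supt6 overlaps Sdf2, Nsd2 overlaps Nelfa and Psip1 overlaps Snapc3, so peaks there may belong to the other gene. Setd2 itself was at 8.59% (19.1% ± 19.2, SD, n = 2), Msh6 at 9.10% and the DNA methyltransferase gene Dnmt3a at 5.89%, while Dnmt3b, Phf19 and Setmar had no replicated peak. The adjusted p was 0.000702 (two-sided exact conditional test, Benjamini-Hochberg over the 22 lists). The call was lost without replicate 2, where 3 were marked (adjusted p = 0.0554, exact test), and with peaks of −log10 q over 4, where 0 were.

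Imprinted genes were not marked more often than others. Of 23 protein-coding members 1 was marked, Nnat (44.2%; 55.8% ± 41.8, SD, n = 2), which overlaps Blcap, so the peak cannot be assigned to 1 of the 2 (1.54 expected, adjusted p = 1, two-sided exact conditional test). The next was Gnas with 7.42%. Of the non-coding members, Rian had 4.97%, Meg3 1.30% and H19 none. Replicate 2 alone marked 9 of the 23.

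Within marked genes, exons carried more of the mark than introns. Over 1892 marked genes with several exons, the median covered share was 27.5% of exon bases and 15.4% of intron bases, and exons were higher in 1382 genes (73.0%). The median difference per gene was 11.3 points (95% bootstrap interval over genes 10.1 to 12.4). A two-sided permutation test of the mean difference by sign flips gave p = 1e-05, the smallest that 100000 flips can give. The median difference was 7.96 points in replicate 1 and 13.1 in replicate 2. Over all genes with any replicated peak it was 4.17 points.

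Genes with 1 exon were marked less often than genes with several. Of 1309 single-exon genes other than Olfr genes, 18 (1.38%) were marked where 51.3 were expected from length, against 1892 of 19410 multi-exon genes (9.75%; two-sided exact conditional test, p = 2.84e-10). The highest, named after their values were seen, were Atxn7l3b (41.5%; chromosome 10, 112925430 to 112929001) and Cstf2t (38%), which overlaps Prkg1. Of the 18, 10 overlap another protein-coding gene, and 8, Atxn7l3b and Pcbp1 (11%) among them, overlap none. With peaks of −log10 q over 4 the difference was no longer past the threshold (-0.334 points, exact p = 0.0862).

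The X chromosome was nearly bare of replicated peaks. Of 941 X-linked protein-coding genes other than Olfr genes, 2 (0.213%) were marked where 79.5 were expected from length, against 1919 of 19679 autosomal genes (9.75%; two-sided exact conditional test, p = 1.37e-34). These were Amer1 (12.8%; X, 95420318 to 95444872) and Gm21887 (20.9%; X, 170009659 to 170019281), both named after their values were seen. Gm21887 lies near the distal end of the X, and whether its sequence is shared with the Y was not examined. Single autosomes ranged from 5.68% on chromosome 14 to 12.8% on chromosome 11. In replicate 1 the X share was 0.106% against 4.79%, and in replicate 2 it was 7.23% against 32.1% (exact p = 2.29e-17 and 7.77e-63), so the X lay below the autosomes in both. Among the genes of X inactivation and their Y-linked relatives, none of 13 protein-coding members was marked (0.924 expected, adjusted p = 0.816, exact test). Of the genes known to escape X inactivation, Ddx3x had 6.93%, Eif2s3x 6.43% and Kdm5c 5.99%, Kdm6a had none, and the silencing RNA Xist had none in the replicated list and 3.31% in replicate 2. None of 183 Y-linked genes was marked, Uty, Ddx3y, Kdm5d and Eif2s3y included. Peak numbers on the X were 122 in replicate 1, 2181 in replicate 2 and 104 in the replicated list.

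**Figure D4:**
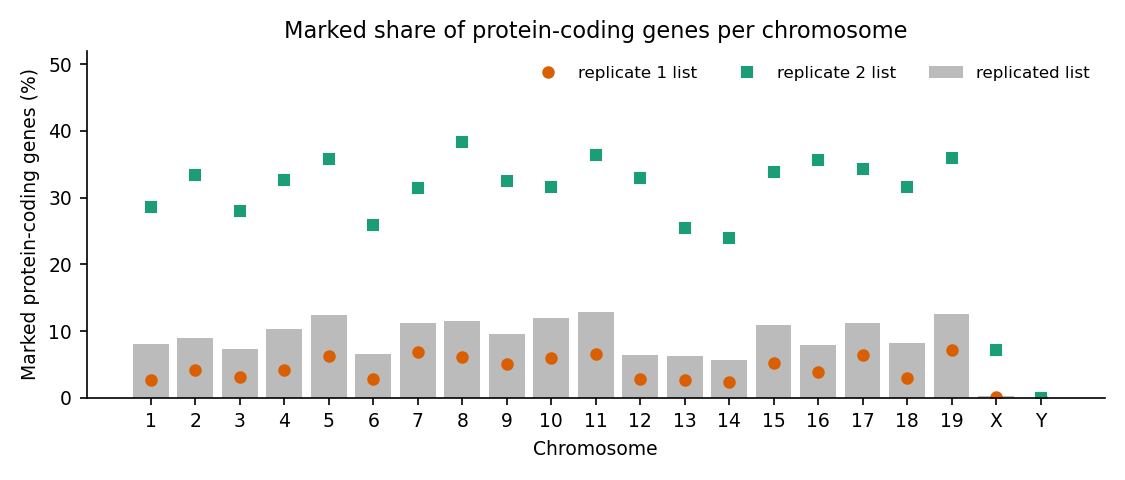
Marked share of protein-coding genes other than Olfr genes (%, vertical axis) on each chromosome (horizontal axis). Bars are the replicated list, circles replicate 1 and squares replicate 2; the X (0.213%, 0.106% and 7.23%) lies below every autosome in all 3 lists.

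A few single peaks and non-coding genes stood out by length or height. The longest replicated peak, 8954 bp on chromosome 1 from 88261300 to 88270253, covered the end of Hjurp and part of Mroh2a, with 41.4% of its bases in 3′ UTR, 37.6% in intron and 19% in coding exon. The next, 7119 bp on chromosome 7 from 24100442 to 24107560, lay in Zfp180, with 54.0% in intron, 25.8% in coding exon and 20.2% in 3′ UTR. The peaks with the highest −log10 p of the replicated list (44.8) and of replicate 2 (65.3) both lay in Mid1 at the distal end of the X, from 169988466 to 169989492 and from 169988466 to 169989471. In replicate 1 the highest (32.1) lay elsewhere, on chromosome 7 from 5029236 to 5032361, at Gm44973, Zfp865 and Ccdc106. Whether the sequence at this end of the X is shared with the Y was not examined. Among non-coding genes of at least 1 kb that overlap no protein-coding gene, the highest covered shares were in Gm26917 (71%), Gm45110 (54.1%), the snoRNA host gene Snhg17 (47.0%), Gm26930 (44.2%) and Mir17hg, the host of the miR-17 cluster (41.4%). Peaks in Gm26917 reached a signal value of only 1.65, against a median of 3.60 over replicated peaks. They covered more of it in replicate 1 (79.4%) than in replicate 2 (69.0%). No filter for repeats or regions of high background was applied here, so coverage of Gm26917 is not shown to be the mark.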

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

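The tests of ubiquitously transcribed X-linked genes against all autosomal genes were chosen after the result was seen, and the other tests in this part were written down before their own values were seen, after the patterns had been noticed in the same data, with that of genes marked in replicate 2 added once the others were known. Outside the assembled chromosomes, which every comparison by gene uses, 16 replicated peaks lay on unplaced or unlocalized scaffolds of mm10, and they were looked at again because no comparison uses them. Of these, 11 (4541 bp) were on Un_JH584304, 3 (4029 bp) on 4_GL456216_random, 1 (635 bp) on 4_JH584295_random and 1 (293 bp) on Un_GL456239.

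The X chromosome held 2 marked genes where 79.5 were expected from gene length. Whether a larger share of tissue-restricted genes on the X is the whole cause is not decided, since the lists of peaks differ. A fixed list of 40 ubiquitously transcribed X-linked genes was compared with all autosomal genes of the same length, tissue-restricted ones included. In the replicated list none (0) was marked, where 4.14 were expected, a difference of -10.3 points (two-sided exact conditional test, p = 0.0292). Of the 22 marked in replicate 2 (Flna, Hcfc1 and Uba1 among them), none was marked in the replicated list against 7.14 expected from the autosomal genes marked in replicate 2 (p = 0.000217) and none in replicate 1 against 3.64 (p = 0.0350, same exact test). The comparison of the 22 shows weaker coverage of these X-linked genes, which a single active X would give as well. Over all 40 in replicate 1 the same exact test did not reach the threshold (0 marked, 2.01 expected, exact p = 0.263). In replicate 2 their 55% lay above the 32.1% of all autosomal genes, the direction that tissue restriction predicts. The test first written down compared them in replicate 2 with 64 autosomal housekeeping, spliceosome and cell cycle genes (-41.9 points, Fisher's exact p = 1.86e-07), but these are among the most marked lists in the same data, so it decides nothing. More repeat sequence on the X is argued against too, since within strata of length and of repeat-masked share the X held 0.0268 of the expected marked genes (exact p = 1.35e-32). A single active X per cell in both sexes, which would put X peaks nearer the authors' calling threshold, may contribute and stays open. Dropping replicate 2 peaks with −log10 p under 4, an assumed profile of fewer reads, left the 64 autosomal genes named above at 96.9% and took the X-linked list from 55% to 40%, a drop that was not tested, and such an assumed cut does not decide the question.

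Replicate 2's list was 5.62 times as long as replicate 1's. Scattered noise is argued against, since 93.5% of the bases under the 152458 replicate 2 peaks that touch no replicate 1 peak lay in gene bodies, where shifted lists gave at most 52.3% (one-sided permutation p = 0.0099). With replicate 2 cut to the same number of peaks, most marked genes of each list held a peak in the other pool too. Of the genes marked in replicate 1, 97% had a peak in replicate 2 (31.8% of all genes). Of the 2662 marked in replicate 2, 92.6% had one in replicate 1 (32.1% of all genes). Still, 1771 of the 2662 fell short of being marked in replicate 1. The cut also takes out the extra peaks to be explained. It therefore does not show whether they lie in genes without a replicate 1 peak. In the full lists, 12034 protein-coding genes held a peak in replicate 2 and 7053 in replicate 1. Genes with peaks or marked in replicate 2 alone are thus not argued against. Lower enrichment or depth of replicate 1 over the same genes is a candidate explanation, with 99.8% of its marked genes also marked in replicate 2. Replicate 1 has 1 technical replicate and replicate 2 has 3, per the labels, and what this adds to the difference was not tested. Enrichment and depth were not separated, and no biological explanation was tested.

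Exons of marked genes carried more of the mark than introns. In windows of 200 bp, exons were covered 16.9 points more than introns, and 80.5% of that difference was kept (95% interval 77.1% to 83.6%) when windows were compared within the same part of the gene, which argues against the position of exons near gene ends as the whole cause. Windows free of repeat-masked bases kept 98.4% and windows of the same GC class 97.1%, so neither repeats nor GC content accounts for it alone. With all 3 matched together 70.5% was kept (63.0% to 77.5%), so position, repeats and GC together may account for part. No biological explanation was tested.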

How the results depend on the processing

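The setting that keeps only replicated peaks found in both replicates and 3 settings of the neural comparison (length strata, the synapse list added, the progenitor list left out) were chosen after the data were seen, and all others before. Under other settings 91 values of the main comparisons kept their direction and side of the threshold (or moved little), 19 moved and 2 became weaker. For single lists 20 values newly passed the threshold, all toward fewer marked genes, 1 lost it, 2 turned and the others stayed the same. Peak numbers depend on the authors' q. With −log10 q over 2 and over 4, replicate 1 had 7088 and 1281 peaks, the pooled list 15235 and 2464 and the replicated list 13783 and 2443, and replicate 2 had 42907 with −log10 q over 4. Marked genes numbered 3190 at 5% covered, 808 at 20%, 6562 with any overlap, 970 with −log10 q over 2 and 272 with −log10 q over 4. Leaving out each replicate in turn gave 943 to 6383 marked genes, the higher number without replicate 1, and with peaks found in both replicates the number was 1322. Lists marked less often than expected numbered 2 at 5% covered, 2 in the pooled list and 2 with replicate 2 at replicate 1's number of peaks (Hox and Olfr each time), 9 with any overlap, and 1 to 10 leaving out each replicate in turn. The cause was not tested for these. With −log10 q over 4, single-exon genes differed from multi-exon genes by -0.334 points (exact p = 0.0862), the cell cycle list fell to -1.39 points from its expectation and the list of H3K36 writers, erasers and readers to -0.580 points (adjusted p = 1 for both), with 0 members marked in each. Few genes are marked at all under that setting, and the cause was not tested. With the progenitor list left out, neural lists exceeded other tissues by only 2.17 points (Fisher's exact p = 0.315), since 7 of the 9 marked neural genes are progenitor genes. Without replicate 2 the H3K36 list also lost its call (adjusted p = 0.0554, exact test). Under every setting run, the share of covered bases in gene bodies stayed between 94.2% and 96.3%, gene ends were covered more than gene starts by 0.469 to 17.5 points, exons exceeded introns by 4.17 to 13.4 points, and the X lay below the autosomes by -1.12 to -22.9 points. With the progenitor list kept, neural lists exceeded other tissues by 5.13 to 31.7 points (p at most 0.0147, Fisher's exact test, or the exact conditional test with length strata). No paired analysis was possible because there is 1 group only. Unknown depth limits all counts of unmarked genes.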

Other observations

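Lists differed in how many members held the peaks with the lowest q. With replicated peaks of −log10 q over 4, 56 of the 397 Zfp genes were marked against 6.72 expected from length (two-sided exact conditional test, adjusted p = 3.42e-35), while none of the 25 cell cycle genes was (0), 5 of 20 housekeeping genes, 6 of 22 spliceosome genes and 4 of 22 neural progenitor genes were. These counts come from a setting fixed before the data were examined, and the differences between the lists were not tested.

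Few genes of non-coding classes were marked, by raw shares that were not tested or matched for length. Of 5854 lincRNA genes 36 (0.615%) were marked, 11 of them outside protein-coding genes, and of 9940 processed pseudogenes 42 (0.423%), 4 of them outside. Of 2959 antisense genes 120 (4.06%) were marked, but none (0) of the 209 that overlap no protein-coding gene, so peaks there cannot be assigned to a strand. Of 1507 small nucleolar RNA genes 91 (6.04%) were marked, 21 of them outside protein-coding genes, and 1 short peak can pass 10% of genes as short as these. More than 5 kb from every annotated gene lay 32 replicated peaks (0.0965%) in 23 clusters. The largest by covered length was on the Y from 90739029 to 90745861 (6 peaks, 3572 bp), 7.195 kb from the pseudogene Mid1-ps1, followed by chromosome 4 from 119271558 to 119272671 (948 bp), between Cldn19 and Ybx1, which ends 5.309 kb away. The next by covered length were on chromosome 14 from 73602249 to 73604201 (890 bp, 6.107 kb from Sucla2), chromosome 5 from 104582331 to 104585762 (725 bp) and chromosome 6 from 38617939 to 38618488 (550 bp, 8.469 kb from Luc7l2). The non-coding gene Gm26917 was covered to 79.4% in replicate 1 and 69.0% in replicate 2, although its peaks reached a signal value of only 1.65.

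Both hypotheses that follow had their tests written down before the values were seen. In zinc finger genes the mark may be denser in the last exon, where such genes usually encode their finger array, than in the rest of the gene. Among genes with at least 5% covered, the last exon exceeded the rest of the gene by 31.3 ± 27.9 points in 153 Zfp genes and 8.96 ± 28.6 in 2993 others (SD over genes), a difference of 22.4 points (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). Peaks covered 45.0% of the last exon in Zfp genes and 22.9% in the others, and 13.7% and 14.0% of the rest. Last exons of the Zfp genes were also longer, with a median of 2873 bp against 1169 bp, and exon length was not matched.

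The mark may also run past the annotated gene end. In 244 marked genes with no other gene within 5 kb, the 5 kb after the end were covered to 4.82% ± 8.31 (SD over genes) and the 5 kb before the start to 0.0328%, a difference of 4.79 points (sign-flip permutation p = 1e-05, the smallest that 100000 flips can give). Of these genes 95 had a peak after the end and 1 before the start. The 1718 marked genes of at least 5 kb were covered 26.3% in bin 10 at the gene end and 1.29% in bin 1. More peaks can therefore reach over the gene end than over the start by their width alone. The comparison thus does not decide whether the mark itself runs past the end. Whether the excess after the end comes from peak width, from longer transcripts than annotated or from transcription past the end was not tested.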
